A study of Mus musculus with 4 samples.

How the data were processed

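Mouse Achilles tendon cells were measured by droplet-based single-cell RNA sequencing in 4 libraries, with 1 library for each of neonate control, neonate injury, adult control and adult injury, grouped by the age and state in the labels. The tissue was digested with collagenase and DNase before barcoding, per the labels. The deposited matrices hold the count of UMIs for each gene and barcode, made with Cell Ranger 8.0.1 per the file headers, against GRCm39 per the submitters' processing notes. They list 33696 genes, and the files have no values other than counts. Of the genes in the lists used here, 4 are absent from the files. Gene symbols that are listed more than once number 52, and the entry listed earliest was used.

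Barcodes with at least 500 genes, at least 1000 UMIs and at most 15% mitochondrial UMIs were kept, which left 10429, 14885, 6113 and 4625 barcodes in the order neonate control, neonate injury, adult control and adult injury. Scrublet, run in scanpy 1.11.5, scored doublets in each library, and the highest scores were removed at 0.8% per 1000 barcodes, which took out 908, 1944, 321 and 185 barcodes. The cells kept had medians of 3490, 2328, 3194 and 3466.5 genes and of 2.13%, 2.38%, 1.88% and 2.68% mitochondrial UMIs. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components and 15 neighbours were used for joint Leiden clustering at resolution 1 without batch correction. Clusters were named from the markers of 23 cell classes, set before the data were examined. A cluster was given the class whose markers were detected in the largest mean share of its cells, when that share was at least 30% and at least 3 of the markers were in at least 25% of cells. It stayed unnamed when markers of another lineage reached 40%, when more of its 10 leading genes were markers of another class, or when its median depth was below 0.333 of that of the library with no marker of its class among these 10 genes. These thresholds were set after the data had been examined. Unnamed clusters of at least 50 cells were clustered again at resolution 0.5. This gave 78 clusters, of which 20 stayed unnamed.

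UMIs were summed over the cells of a class in each library and given as CPM. Ratios are log2 ratios of CPM with 0.5 counts added, with intervals from the exact binomial distribution of the counts; CPM intervals are exact Poisson and share intervals exact binomial, all at 95%. Since each group held 1 library, no test between groups was run and no genes were called changed. The comparisons were neonate control against adult control, injury against control at each age, and the difference of the injury log2 ratios, neonate minus adult. The classes compared, chosen before the data were examined, were fibroblast lineage, macrophage-like and endothelial-like cells, each with at least 100 cells in every library. Mural cells (603, 386, 431 and 126) also reached this number but their genes were not compared. For 40 gene lists, set before the data were examined, the median log2 ratio of members with at least 50 UMIs was set against 10000 random lists matched in expression over 20 bins, with order-statistic intervals. A fold against 0 counts is a lower bound at a floor of 3 counts. Dividing cells were those with at least 2 G2M UMIs after thinning each cell to 1000 UMIs. For the removal of cycling cells, the 2 G2M UMIs were counted without thinning.

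Genes were named by a rule: in each comparison the 10 highest and 10 lowest ratios in the fibroblast lineage, and the 5 highest and 5 lowest in the other classes, among genes with at least 50 CPM in the higher library, and up to 4 members with the largest absolute ratio for each list described. Some genes were left out of the highest and lowest genes. These were mitochondrial, ribosomal protein, predicted, hemoglobin, X-inactivation and Y-linked genes, markers of other classes and genes over 10 times higher in another class. Other genes of the X chromosome were kept. Members of lists that are over 10 times higher in another class, and so can be free RNA, were passed over or named as such. A few genes that the rule picks are not reported here.

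The steps from counts to ratios were tested on simulated data, with 100 genes at 2-fold and 100 at 4-fold in the counts of each class. Class totals were drawn from the Poisson distribution that the intervals assume, without variation between cells. Coverage near 95% was thus set by the model. The simulation checks the steps and cannot show that the intervals hold for real cells. In the fibroblast lineage the interval held the true ratio for 94% and 92% of these genes in the age comparison (16155 genes), 98% and 96% in the neonatal injury comparison (16517 genes) and 93% and 97% in the adult one (15416 genes). In macrophage-like cells it held 95% and 93% (8631 genes), 95% and 97% (10030 genes) and 91% and 98% (10086 genes). In endothelial-like cells it held 98% and 97% (9969 genes), 97% and 96% (10044 genes) and 95% and 97% (10276 genes). A list of 20 genes at 2-fold had medians of 0.97, 0.98 and 0.99 in the fibroblast lineage. Of 100 unchanged lists, 6, 2 and 3 lay outside the central 95% of random lists.

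Alternatives fixed before the data were examined were a looser and a stricter cell filter, doublets kept, resolutions 0.5 and 2, clustering of each library alone, median-of-ratios scaling, no minimum count, the mean of per-cell CPM, thinning to 1000 UMIs, tenocyte-like or fibroblast-like cells alone, removal of cycling cells, and thinning to 500 or 2000 UMIs for the cycling share. Unnamed clusters counted in their closest class, neonate injury cells with Y-linked UMIs and no Xist, and lists without free-RNA members were chosen after seeing the data. The analysis used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9.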

Results

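Mouse Achilles tendons, which join the calf muscles to the heel bone, were profiled by droplet-based single-cell RNA sequencing in 4 libraries. The libraries came from neonates at postnatal day 3 and from adults aged 6 to 8 weeks, each age with an uninjured control library and an injured library. There was 1 library per group, so no difference below has a replicate check. Shares, CPM and ratios of single genes or marker sums are given with exact 95% intervals that cover counting error only. Intervals of list medians are order-statistic intervals over the member genes. They describe the spread among genes of the same summed cells, not counting error or replicates. The time from injury to harvest, the number of mice per library and their sex are not given in the labels. The labels also do not say whether the age of an injured library is that at injury or at harvest. Injured mice can thus have been older than their controls when harvested. The matrices held 38780 barcodes with 369063404 unique molecular identifiers (UMIs). The totals were 128626912 UMIs in the neonate control library, 100169054 in the neonate injury library, 68644322 in the adult control library and 71623116 in the adult injury library. After removal of low-quality barcodes and likely doublets, 9521, 12941, 5792 and 4440 cells remained in that order. Their median depths were 10333, 5541, 9535.5 and 10197.5 UMIs.

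The makeup of the tendon was compared first, to ask which cell types differ in share with age and with injury. Fibroblast-lineage cells, that is tenocyte-like and fibroblast-like clusters together, made up 55.6% [54.6, 56.6] of cells in the neonate control and 62.5% [61.6, 63.3] in the neonate injury library. In adults they made up 64.6% [63.4, 65.9] of control cells and 41.7% [40.2, 43.1] of injured cells. Macrophage-like cells, phagocytes that clear debris, were at 3.16% [2.82, 3.53] in the neonate control and 9.85% [9.34, 10.4] after neonatal injury. The adult values were 2.87% [2.45, 3.33] and 25.1% [23.8, 26.4]. All named immune classes together accounted for 6.37%, 11.9%, 4.64% and 34.8% of cells in the order neonate control, neonate injury, adult control and adult injury. Neutrophil-like cells were at 3.04% in the injured adult library against 0.069% in its control, and at 0.100% in the injured neonate library against 1.04% in its control. With the stricter filter the injured adult library was at 1.77% and the injured neonate library at 0.017%. With each library clustered alone, no cells of the injured neonate or the adult control library were named neutrophil-like. Endothelial-like cells, which line vessels, were at 3.03% and 6.58% in neonates and at 13.1% and 7.37% in adults, control before injury. These shares depend on the clustering: with unnamed clusters counted in their closest class they were 4.59% and 7.84% in neonates and 14.2% and 10.9% in adults, and with each library clustered alone the neonatal order turned, to 4.60% and 2.54%. Schwann-like cells, the glia of peripheral nerve, were at 5.71% and 9.99% in neonates and at 1.38% and 0.315% in adults. Chondrocyte-like cells were at 8.89% in the neonate control and 0.263% in the neonate injury library (0.103% with the looser and 0.059% with the stricter filter). In the same order, myogenic progenitor-like cells were at 8.17% and 1.93%, erythroid ones at 0.966% and 0.015% and myofibre ones at 0.746% and 0.162%. Osteoblast-like cells numbered 31 and 0. Lymphatic endothelial-like cells (0.315% and 0.827%) and T or NK cells (0.168% and 0.858%) went the other way. The cause of these differences was not tested. None of the 5792 adult control cells was chondrocyte-like, with an exact upper limit of 0.064%. The same held for the 4440 adult injury cells, with an upper limit of 0.083%. Clusters left unnamed held 1.85%, 2.36%, 1.81% and 11.5% of cells in the same order of libraries.

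**Figure D1:**
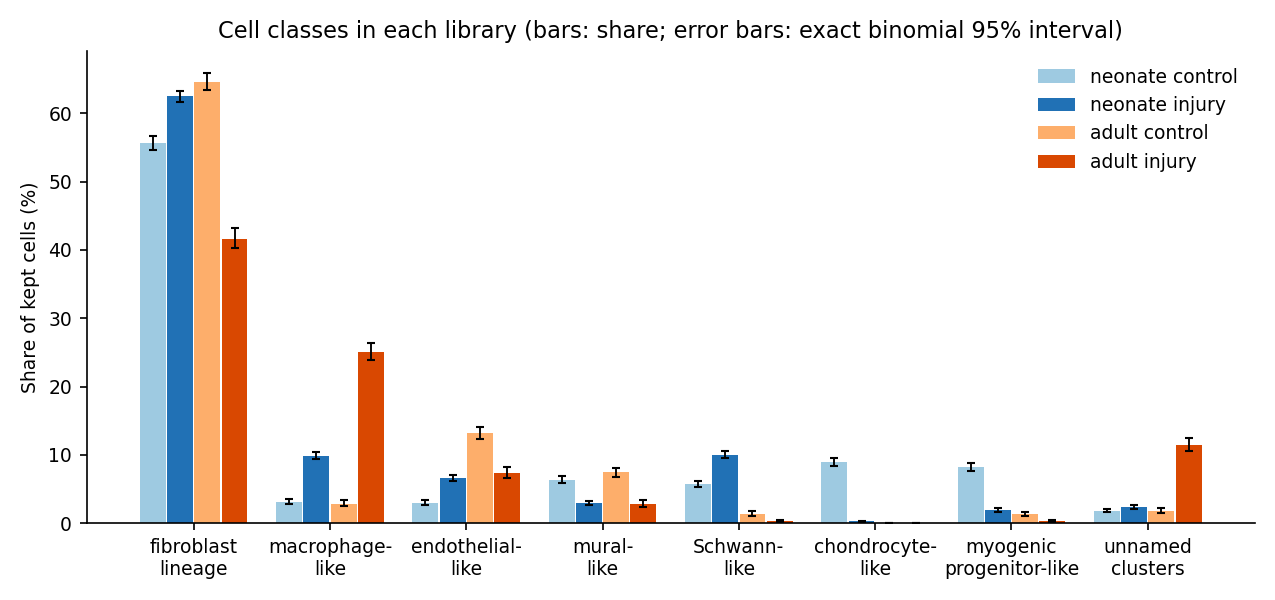
Share of cells, in percent of all cells kept, for the named classes in each of the 4 libraries, with exact binomial 95% intervals as error bars. Macrophage-like cells reached 25.1% in the injured adult library and 9.85% in the injured neonate library, and the fibroblast-lineage share was lowest, at 41.7%, in the injured adult library.

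The split of the lineage into tenocyte-like and fibroblast-like cells is descriptive, because it rests on markers whose own level differed between libraries. Tenocyte-like cells were at 10.5% of the neonate control, 22.6% of the neonate injury, 39.7% of the adult control and 3.63% of the adult injury library. Fibroblast-like cells were at 45.2%, 39.9%, 24.9% and 38.0% in the same order. The neonatal tenocyte-like shares, control before injury, were 12.8% and 19.2% at resolution 2 and 9.51% and 23.6% with the stricter filter. Different clusters held most of each class in different libraries. Among tenocyte-like cells, clusters 17 and 4 held 53.8% and 28.0% in the neonate control, and clusters 5 and 4 held 46.3% and 40.0% after neonatal injury. Cluster 5 took 94.7% of its cells from the neonate injury library, and none of its 10 leading genes was a tenocyte marker. Cluster 3 held 72.2% of tenocyte-like cells in the adult control, and cluster 21 held 63.4% of the 161 left after adult injury. Among fibroblast-like cells, cluster 1 led in the neonate control with 35.5%, cluster 0 in the neonate injury library with 41.9%, cluster 11 in the adult control with 63.3% and cluster 7 in the adult injury library with 75.3%. Cluster 7 took 97.2% of its cells from the injured adult library and cluster 3 took 98.8% from the adult control; a cluster of 1 library cannot be told from that library itself. Xist, transcribed from the inactive X chromosome of females, and Y-linked transcripts also differed between libraries. Cells with Xist and no Y-linked UMIs made up 0.019% of fibroblast-lineage cells in the neonate control, 76.2% in the neonate injury library, 94.8% in the adult control and 91.5% in the adult injury library. Cells with Y-linked UMIs and no Xist made up 86.6%, 14.4%, 0% and 0.054%, with 0 of 3743 cells in the adult control. Every comparison with the neonate control is therefore also one between mostly Y-positive and mostly Xist-positive cells.

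Uninjured neonates were set against uninjured adults to ask how resident tendon cells differ with age. In fibroblast-lineage cells the neonate library stood above the adult library in imprinted growth genes and in cell cycle genes. Dlk1 (ENSMUSG00000040856), a paternally expressed inhibitor of differentiation, was at 2502 counts per 1000000 UMIs of the class (CPM) [2490, 2514] in neonates and 3.91 CPM [3.35, 4.53] in adults, a log2 ratio of 9.32 [9.11, 9.55]. The imprinted RNA H19 was at 2039 and 6.89 CPM, a log2 ratio of 8.21 [8.05, 8.37], and the growth factor gene Igf2 had a log2 ratio of 7.38 [6.83, 8.07]. The angiotensin receptor gene Agtr2 (7.35), the kinase gene Nrk (6.02) and the imprinted genes Zim1 (6.07), Slc38a4 (5.81) and Mest (5.79) were also among the 10 highest, together with the mitotic genes Cdk1 (6.15) and Top2a (5.70). Dlk1, Nrk and Zim1 are leading genes of cluster 1, which held 35.5% of fibroblast-like cells in the neonate control. Of the 14 measured genes of the imprinted growth network, 13 were at least 2-fold higher in neonates and 0 lower, with a median log2 ratio of 4.67 [2.40, 7.38]. All 20 G2M genes, which act in mitosis, were at least 2-fold higher, with a median of 5.06 [4.27, 5.68]; Aurkb (6.16) and Bub1 (5.78) were examples. The median was 2.06 without the cells that hold at least 2 G2M UMIs. Of 18 S phase genes, which act in DNA replication, 15 were at least 2-fold higher with a median of 2.32 [1.27, 3.13], among them Dtl (4.06), Mcm5 (3.37) and Gins2 (3.16).

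At the adult end of the same comparison, genes of secreted proteins were among those with the largest differences. Angptl7 (ENSMUSG00000028989), a secreted angiopoietin-like protein, was at 5.79 CPM [5.21, 6.42] in neonates and 5874 CPM [5852, 5897] in adults, a log2 ratio of -9.98 [-10.14, -9.84]. Chad, a leucine-rich matrix protein, was at 5.47 and 2515 CPM (-8.84 [-9.00, -8.69]), and the secreted phospholipase gene Pla2g5 had 2 UMIs in neonates and 2244 in adults (-10.29 [-13.66, -8.76]). S100g (-9.41), Galnt15 (-8.13), C7 (-7.40), Myoc (-7.21), Clu (-6.54) and Ptprt (-6.21) were also among the 10 lowest. Angptl7, Chad, Clu and Myoc are also leading genes of cluster 3, so these values move with that cluster; C7 turned to 0.36 in tenocyte-like cells alone. Complement genes, which opsonise and lyse targets, were lower in neonates, with 8 of 11 at least 2-fold lower, 0 higher and a median of -1.66 [-6.78, -0.64]; C3 had a log2 ratio of -5.73 and Masp1 of -3.14. In fibroblast-like cells alone that median was -2.52. Genes of the thyroid, glucocorticoid and circadian response had a median of -2.00 [-3.68, -0.32] with 9 of 13 at least 2-fold lower, among them the clock output gene Dbp (-4.04), the thyroid hormone receptor gene Thrb (-3.96) and the glucocorticoid-induced Tsc22d3 (-3.68).

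Matrix and metabolic groups divided between the ages. Of 12 tendon transcription factors and markers, 8 were at least 2-fold lower in neonates and 2 higher, with a median of -1.83 [-3.96, 0.28]. Cilp2 had a log2 ratio of -6.06, the cartilage oligomeric protein gene Comp was at 48.3 and 2250 CPM (-5.54) and Fmod, a small proteoglycan that binds collagen fibrils, at 185 and 2867 CPM (-3.96). The tendon median was -0.73 in tenocyte-like cells alone and turned to 0.96 in fibroblast-like cells alone. Fibrillar and fibril-associated collagens had a median of 0.93 [-0.41, 1.68], or 1.40 in fibroblast-like cells alone, with Col5a1 (2.25) and Col3a1 (2.22) higher and Col22a1 (-2.83, or 0.94 in fibroblast-like cells alone) lower in neonates. Cholesterol synthesis genes were higher, with 11 of 13 at least 2-fold up and a median of 1.94 [1.26, 2.54], among them Idi1 (2.98), Sqle (2.84), Cyp51 (2.54) and Hmgcs1 (2.40). Heat shock genes, which encode chaperones, had a median of 1.08 [0.93, 2.15] with 8 of 12 at least 2-fold higher, including Hsph1 (2.50), Dnajb1 (2.15) and Hspa1a (2.16), whose counts are uncertain because its transcript is nearly identical to that of Hspa1b. These medians lay below the 1st or above the 99th percentile of 10000 matched random lists, which describe these libraries only. The neonate control is also the reference of the neonatal injury comparison below, so those ratios are not independent of these. The adult control is likewise the reference of both the age and the adult injury comparison. A gene low or high in that library moves both ratios the same way. Markers of other cells moved with age inside the same lineage. Such sums, here and below, were not split by gene and can include RNA that the class makes itself. Synovial lining markers summed to 224 CPM in neonates and 5016 in adults, dendritic markers to 143 and 26.1, myofibre markers to 337 CPM in neonates and 12.0 in adults, neutrophil markers to 14.8 and 1.50, macrophage markers to 18.9 and 8.33, and osteoblast markers, which include Spp1, to 43.9 and 1207. The median gene had a log2 ratio of 0.12 over 16151 genes.

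**Figure D2:**
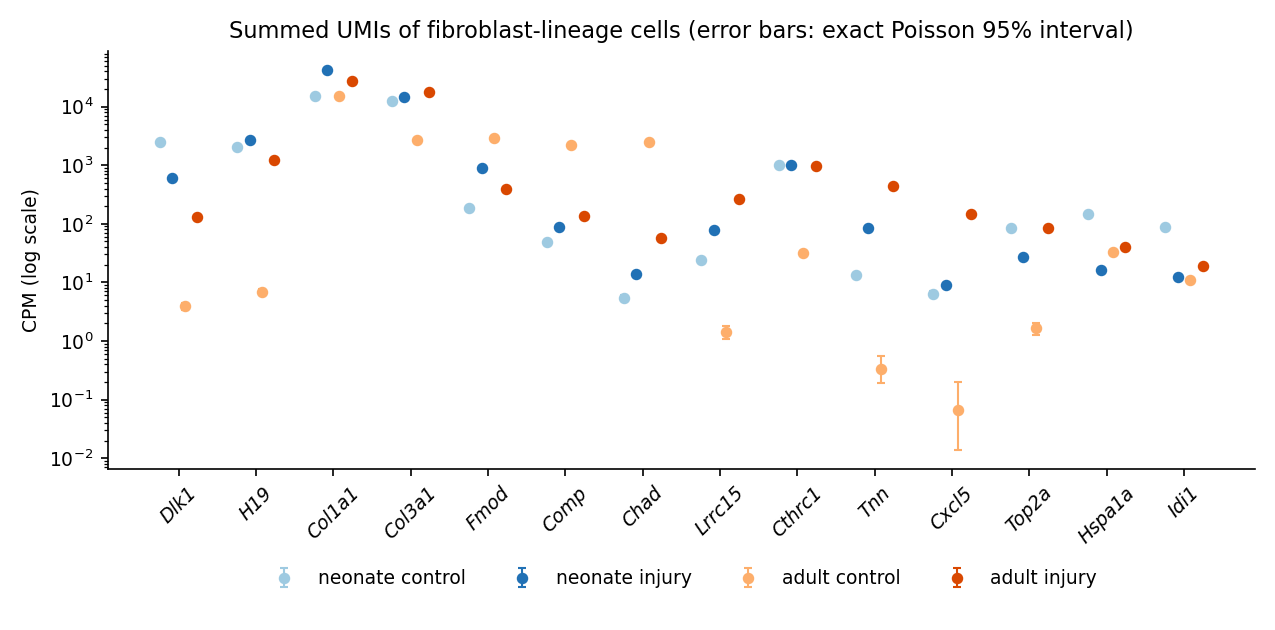
CPM of named genes in fibroblast-lineage cells of the 4 libraries, on a log axis, with exact Poisson 95% intervals as error bars. Dlk1 stood at 2502 CPM in the neonate control and 3.91 CPM in the adult control, and Chad at 5.47 and 2515 CPM.

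In neonates the injured library was set against its control to ask how the young tendon responds. Fibroblast-lineage cells of the injured library stood above the control in the median of collagen and interferon response genes and below it in cell cycle, heat shock and cholesterol synthesis genes. Edil3, an integrin ligand of the matrix, was at 104 CPM [101, 107] after injury and 8.38 CPM [7.68, 9.13] in the control (log2 ratio 3.63 [3.50, 3.76]), and the prolactin receptor gene Prlr at 104 and 11.8 CPM (3.14 [3.03, 3.25]). Brinp3 (3.10), Matn4 (2.87), Gpx3 (2.73), Tnn (2.66), Sema3b (2.38) and Lsp1 (2.31) were also among the 10 highest, as was Fmod at 906 and 185 CPM (2.30 [2.27, 2.32]). Prlr leads cluster 0, which took 93.2% of its cells from the injured neonate library. Of 12 fibrillar and fibril-associated collagens, 4 were at least 2-fold higher and 0 lower, with a median of 0.63 [0.26, 1.31]; Col1a1, the main collagen of tendon, had a log2 ratio of 1.50 and Col1a2 of 1.18. In fibroblast-like cells alone the collagen median was 0.41. Tendon markers had a median of 0.59 [-0.59, 1.49] with 4 of 12 at least 2-fold higher, including Cilp2 (2.22), Kera (1.49) and Mkx (1.29); in tenocyte-like cells alone it turned to -0.18, and it was 0.03 in fibroblast-like cells alone and 0.29 without free-RNA members. Matrix proteases and inhibitors had a median of 1.17 [-0.07, 1.34] with 9 of 17 at least 2-fold higher, among them the metalloproteinase genes Mmp3 (2.12), Mmp19 (1.87) and Mmp2 (1.84), and the median was 0.53 with doublets kept and 0.72 in injured cells with Y-linked UMIs and no Xist. Interferon response genes had a median of 0.64 [0.11, 1.47] with 6 of 17 at least 2-fold higher, including Ifit1 (1.86), Oasl2 (1.80) and Gbp2 (1.70), and the median was 0.20 in tenocyte-like cells alone and 1.21 in injured cells with Y-linked UMIs and no Xist.

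The genes that were lower after neonatal injury included chaperone, cholesterol synthesis and cell cycle genes. The 10 lowest were the linker histone gene H1f4 (-3.46), Hspa1a (-3.21 [-3.31, -3.11], 16.2 against 149 CPM), Igfbp2 (-2.88), Idi1 (-2.84), Nalf1 (-2.65), Rgs16 (-2.57), Hspb1 (-2.45), Hsph1 (-2.42), Cyp51 (-2.24) and Cebpd (-2.24). The counts of Hspa1a and H1f4 are uncertain because each has close copies. Of 12 heat shock genes, 9 were at least 2-fold lower and 0 higher, with a median of -1.68 [-2.42, -0.88]. Of 13 cholesterol synthesis genes, 7 were at least 2-fold lower with a median of -1.51 [-2.15, -0.56], Fdps (-2.15) and Sqle (-1.97) among them, and the median was -0.93 in tenocyte-like cells alone. The G2M median was -1.64 [-1.71, -1.36] with 18 of 20 genes at least 2-fold lower, including Cdc20 (-2.16), Cdk1 (-2.13) and Bub1 (-2.00), and -0.39 without the cells that hold at least 2 G2M UMIs. S phase genes had a median of -1.26 [-1.44, -1.01] with 14 of 18 at least 2-fold lower, Tyms (-1.93) and Mcm3 (-1.75) among them. Ribosome biogenesis genes had a median of -0.76 [-1.05, -0.39], with Fbl at -1.34 and Ncl at -1.17, and oxidative phosphorylation genes one of -0.71 [-0.92, -0.08], with Ndufv1 at -1.21 and Sdhb at -1.17. The oxidative phosphorylation median was -0.47 in tenocyte-like cells alone. Erythroid markers stood at 1336 CPM in the injured library and 423 in its control, myofibre markers at 38.3 and 337, and neutrophil markers at 1.10 and 14.8. Xist-positive cells were in the majority only in the injured library of this pair.

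In adults the injured library was set against its control to ask the same question of mature tendon. Fibroblast-lineage cells of the injured library stood above the control in cell cycle and myofibroblast genes and below it in tendon markers. The chemokine gene Cxcl5, a neutrophil attractant, was at 145 CPM [141, 148] after injury, with 3 UMIs in the control (log2 ratio 10.85 [9.52, 13.35]). Tnn (ENSMUSG00000026725), the matrix protein tenascin-W, was at 439 CPM [433, 445] and 0.337 CPM [0.189, 0.556] (10.30 [9.62, 11.18]), the interleukin-33 receptor gene Il1rl1 at 280 and 0.427 CPM (9.32 [8.71, 10.09]) and Lrrc15 at 268 and 1.41 CPM (7.55 [7.21, 7.95]). The imprinted RNA H19 (7.45), Kif26b (5.66) and the cycling genes Pclaf (6.36), Top2a (5.67), Mki67 (5.58) and Cenpf (5.33) made up the rest of the 10 highest. Cxcl5, Tnn, Lrrc15 and Kif26b are leading genes of cluster 7, so these values move with that cluster. All 20 G2M genes were at least 2-fold higher with a median of 5.22 [4.25, 5.58], including Ccnb1 (5.88), Ccna2 (5.80) and Aurkb (5.77), and the median was 1.42 without the cells that hold at least 2 G2M UMIs. S phase genes had a median of 1.80 [0.75, 2.84] with 12 of 18 at least 2-fold higher, such as Uhrf1 (5.75), Mcm5 (3.59) and Mcm2 (3.28), and 0.73 with each cell thinned to 1000 UMIs or 0.59 without those cells. Of 12 myofibroblast genes, which mark contractile and matrix-forming cells, 11 were at least 2-fold higher and 0 lower, with a median of 2.55 [1.88, 4.91]; Actg2 (5.53), Cthrc1 (4.91, 967 against 32.2 CPM) and Cnn1 (4.31) were examples. That median was 3.82 in fibroblast-like and 1.76 in tenocyte-like cells alone, and 1.86 without cycling cells. Mural markers in the lineage moved with it, at 595 CPM after injury and 184 in the control, and Actg2 and Cnn1 are also leading genes of mural cluster 22. Acta2 is in both the mural and the myofibroblast list, so the mural sum is not independent of that list.

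Matrix groups of the adult injury comparison differed among themselves. Collagens had a median of 1.18 [-0.22, 2.72] with 7 of 12 at least 2-fold higher, Col5a3 (3.41), Col5a1 (3.36) and Col3a1 (2.72) among them, and 2.14 in fibroblast-like cells alone. Collagen processing and crosslinking genes had a median of 1.14 [0.21, 1.82] with 9 of 16 at least 2-fold higher and 1 lower, including the collagen chaperone gene Serpinh1 (2.38) and the crosslinking enzyme gene Loxl1 (2.12), with Loxl4 lower (-2.01). Matrix proteases and inhibitors had a median of 1.01 [0.20, 2.51] and 0.46 in fibroblast-like cells alone, and the matricellular genes Tnc (3.91) and Postn (3.66) stood higher within a list whose median was 0.33 [-0.58, 3.02]. Chemokine genes had a median of 2.88 [0.65, 3.92] with 13 of 19 at least 2-fold higher, and 1.39 in tenocyte-like cells alone. Of these, Ccl5, Ccl9 and Ccl4 stood over 10 times higher in another cell class and so can be free RNA. Macrophage markers in the lineage summed to 47.2 CPM after injury and 8.33 CPM in the control, and neutrophil markers to 13.7 and 1.50. Dendritic markers summed to 197 and 26.1 and those of T or NK cells to 3.76 and 0.404. Mast cell markers (1.25 and 2.43) and osteoclast markers (266 and 325) went the other way.

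Tendon markers and other genes that were high in the adult control were lower in the injured adult library. Coch, a secreted matrix protein, was at 0.340 CPM [0.190, 0.560] after injury and 106 CPM [103, 109] in the control (-8.24 [-9.13, -7.57]), the leptin receptor gene Lepr at 2.35 and 193 CPM (-6.35 [-6.65, -6.08]) and Angptl7 at 80.6 and 5874 CPM (-6.19 [-6.24, -6.14]). Clu (-6.18), Galnt15 (-6.15), Slurp1 (-6.15), S100g (-5.79), Myoc (-5.76), Fgf9 (-5.46) and Chad (-5.46) completed the 10 lowest. Angptl7, Clu, Myoc and Chad are leading genes of cluster 3, so these values move with that cluster. It held 1660 cells of the adult control and 20 of the adult injury library. Slurp1 is a leading gene of synovial lining cluster 29, which held 93 and 4 cells in the same order. Of 12 tendon transcription factors and markers, 10 were at least 2-fold lower and 1 higher with a median of -2.53 [-3.83, -1.18], including Cilp2 (-4.50), Comp (-4.08), Ptx4 (-3.83) and Fmod (-2.84). This direction turned within the classes: the median was 0.09 in tenocyte-like cells alone and 1.09 in fibroblast-like cells alone, and Fmod was at 0.10 and 0.87. BMP and GDF signalling genes had a median of -1.74 [-2.16, -1.38] with 14 of 15 at least 2-fold lower, including the growth factor genes Bmp4 (-3.62) and Gdf5 (-3.16) and the target gene Id1 (-2.53), whereas the antagonist gene Grem1 was higher (2.43); the median was -0.60 in tenocyte-like cells alone, where Grem1 was at -0.62, and Gdf5 was at 3.95 in fibroblast-like cells alone. Small leucine-rich proteoglycans had a median of -1.95 [-2.84, 0.61], with Omd at -4.45; the median was 0.19 in tenocyte-like and -0.42 in fibroblast-like cells alone and -1.04 with each cell thinned to 1000 UMIs. Thyroid, glucocorticoid and circadian response genes had a median of -1.62 [-4.10, -0.95] with 10 of 13 at least 2-fold lower, including Zbtb16 (-4.78), Tsc22d3 (-4.10) and Dbp (-2.90). Synovial lining markers in the lineage moved the same way, at 567 CPM after injury and 5016 in the control, as did osteoblast markers at 309 and 1207 and erythroid markers at 22.9 and 275.

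**Figure D3:**
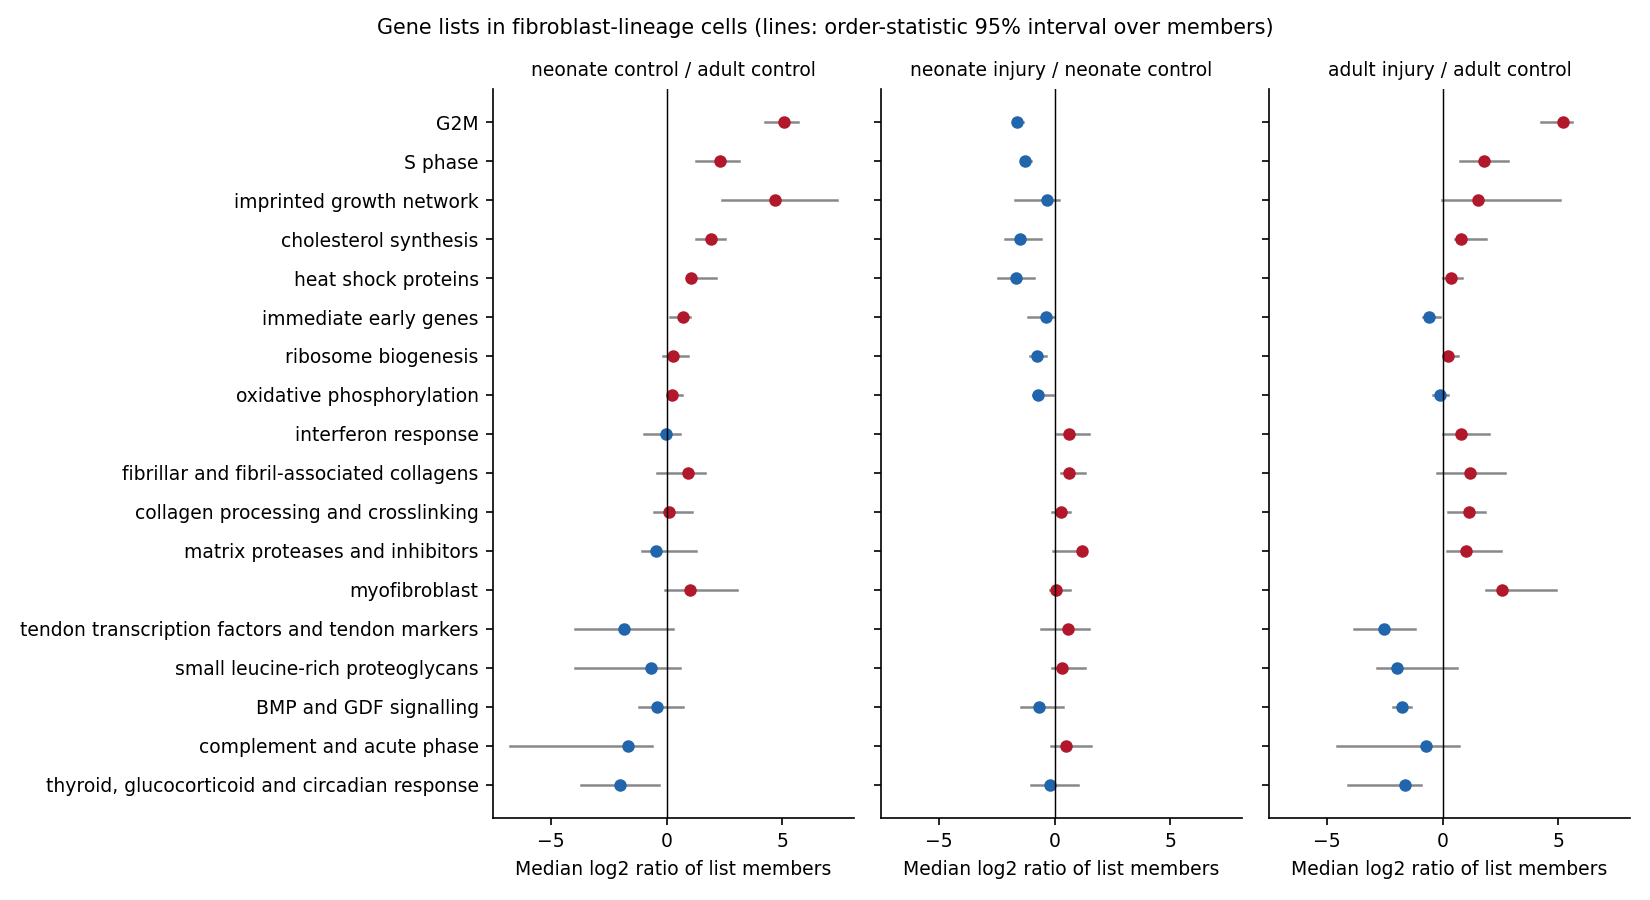
Median log2 ratio of gene lists in fibroblast-lineage cells for the age comparison and the injury comparisons of neonates and adults, with order-statistic 95% intervals over list members as error bars. The G2M list lay at 5.06, -1.64 and 5.22 and the tendon list at -1.83, 0.59 and -2.53.

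The injury ratios of the 2 ages were then subtracted, neonate minus adult, to ask where the responses differ. The difference has no replicate error and was not tested. The G2M list had a median difference of -6.56 [-7.23, -5.86], from -1.64 in neonates and 5.22 in adults, and S phase genes one of -3.05 [-4.11, -2.29], from -1.26 and 1.80; without the cells that hold at least 2 G2M UMIs these were -0.65 and -1.49. Myofibroblast genes had a difference of -2.74 [-4.93, -1.50], since the neonatal median was 0.07 [-0.20, 0.66] and the adult one 2.55, or -4.28 in fibroblast-like cells alone. Cholesterol synthesis genes had a difference of -2.63 [-3.49, -1.52], from -1.51 and 0.80, and -1.56 in tenocyte-like cells alone, where the adult median was 0.42; that adult median was 0.44 without cycling cells and 1.24 in fibroblast-like cells alone. Heat shock genes had a difference of -1.83 [-2.78, -1.15], from -1.68 and 0.36. Tendon markers lay the other way at 2.94 [1.01, 4.97], but turned to -0.68 in tenocyte-like cells alone and -1.03 in fibroblast-like cells alone. Of the 40 lists, 3 had an interval above 0 and 11 an interval below 0.

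Dividing cells were counted directly as cells with at least 2 G2M UMIs after thinning each cell to 1000 UMIs, which left out 0 cells of this lineage. In fibroblast-lineage cells this share was 7.57% [6.87, 8.31] in the neonate control and 2.72% [2.38, 3.10] in the neonate injury library. In adults it was 0.240% [0.110, 0.456] in the control and 9.24% [7.96, 10.7] after injury. Without thinning the shares were 33.0%, 8.36%, 2.78% and 43.9%, at median depths of 10876.5, 6206, 11206 and 20969 UMIs. Neutrophil-like cells, which do not divide once mature, gave 7 of 251 cells over the libraries, a share of 2.79% [1.13, 5.66], at median depths between 1560 and 4561 UMIs. Their cluster is led by the precursor genes Ngp and Camp among others, and its share lay above that of adult control fibroblast-lineage cells, so it sets no lower limit for division. Among macrophage-like cells the shares were 13.6% [9.96, 18.0] and 4.16% [3.13, 5.41] in neonates and 0.602% [0.015, 3.31] and 2.69% [1.82, 3.82] in adults. Without thinning they were 47.5%, 11.9%, 12.7% and 18.0%. Among endothelial-like cells they were 12.8% [9.21, 17.3] and 12.0% [9.87, 14.3] in neonates and 0.394% [0.081, 1.15] and 8.26% [5.51, 11.8] in adults, and 43.4%, 24.8%, 1.97% and 25.4% without thinning. The neonatal pair gives no direction for this class. Its G2M median after neonatal injury was 0.53 [-0.07, 0.72], but -1.12 with the stricter filter, -0.99 at resolution 0.5, -1.09 at resolution 2, -0.16 with each library clustered alone and -1.19 with unnamed clusters included. Cluster 26.0, left unnamed as mixed with mural cells, held 147 cells of the neonate control against 288 named endothelial-like ones.

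**Figure D4:**
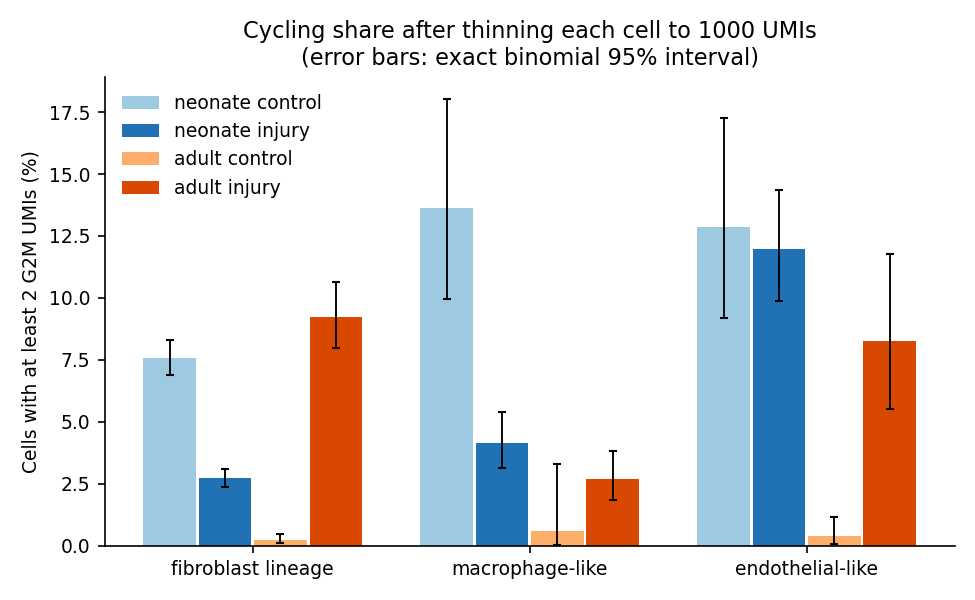
Share of cells with at least 2 G2M UMIs, in percent, after thinning to 1000 UMIs per cell, by library and cell class, with exact binomial 95% intervals as error bars. In fibroblast-lineage cells the share was 7.57% and 2.72% in the neonate control and injury libraries and 0.240% and 9.24% in the adult ones.

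Macrophage-like cells of the injured libraries had their highest ratio to control in Mmp12 at both ages, and the median of lipid-associated genes lay above 0. Mmp12, a macrophage elastase, was at 166 CPM [156, 176] against 1.72 CPM [0.631, 3.75] in neonates (log2 ratio 6.48 [5.47, 8.04]) and at 564 CPM [549, 580] with 1 UMI in the control in adults (9.45 [7.55, 15.34]). In neonates the other highest genes were Saa3 (5.78 [5.14, 6.60]), the fungal receptor gene Clec7a (3.95), the cholesterol exporter gene Abcg1 (3.60) and Mmp14 (3.49). The lowest were Ccn1 (-3.50), Cdk1 (-2.86), Akr1b8 (-2.83), Npl (-2.67) and the ficolin gene Fcna (-2.55). In adults the other highest genes were Ptgs2 (7.31 [5.99, 9.81], 3 UMIs in the control), Flrt3 (6.99), Cxcl3 (6.75) and the fatty acid-binding protein gene Fabp5, at 1238 and 11.9 CPM (6.67 [6.11, 7.38]). The lowest were Zbtb7c (-6.33), Kcnip4 (-5.79), Vsig4 (-5.48), Ildr2 (-5.13) and Timd4 (-4.87). The lipid-associated list had a median of 0.70 [0.02, 2.41] in neonates with 5 of 13 at least 2-fold higher, including Gpnmb (2.79), Spp1 (2.69) and Lpl (2.41), and of 1.89 [0.62, 6.16] in adults with 10 of 13, including Spp1 (6.41) and Gpnmb (6.16). Resident or repair-associated genes had a median of -0.46 [-1.54, 0.94] in neonates, with Lyve1 at -3.28 and Cd163 at -2.16 but Retnla at 4.96, and of -1.19 [-3.55, 0.22] in adults, with Lyve1 at -5.30 and Cd163 at -3.55.

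Inflammatory and interferon groups were also compared in macrophage-like cells. Inflammatory macrophage genes had a median of -0.24 [-0.97, 0.55] in neonates and 1.74 [0.84, 3.48] in adults, where Nlrp3, a component of the inflammasome, had a log2 ratio of 3.48 and Cxcl10 of 2.78. Markers of other immune cells moved with adult injury in this class, dendritic ones at 1545 against 266 CPM, monocyte ones at 521 against 159, neutrophil ones at 106 against 12.4 and those of T or NK cells at 76.6 against 9.15. They did so with neonatal injury as well, dendritic ones at 340 against 112 CPM, monocyte ones at 273 against 53.0, neutrophil ones at 77.7 against 24.9, those of T or NK cells at 49.0 against 6.02 and those of B cells at 229 against 37.8. Interferon response genes had medians of 0.42 [0.03, 1.06] and 1.50 [0.48, 2.12]; the median difference of -0.54 was -0.06 in injured neonate cells with Y-linked UMIs and no Xist. Circadian and glucocorticoid genes had medians of -0.28 [-0.84, 0.27] and -1.67 [-2.92, -1.08], with Fkbp5 at -3.22 in adults. Heat shock genes had a median of -1.16 [-1.52, -0.58] in neonates, which was -0.65 in injured cells with Y-linked UMIs and no Xist, and of 0.08 [-0.11, 0.52] in adults. G2M genes had a median of -1.78 [-1.96, -1.60] in neonates, with all 20 at least 2-fold lower, and 3.52 [2.20, 4.59] in adults, or 2.88 with genes of 0 counts at their bound. Between the uninjured ages, Pclaf, Ube2c and Cdca3 had 0 UMIs in adults and were at least 55.6-fold, 47.7-fold and 33.7-fold higher in neonates against a floor of 3 counts; Cdk1 (7.20 [5.30, 13.09], 1 UMI in adults) and the iron exporter gene Slc40a1 (6.67) followed. Retnla (-8.81), Ildr2 (-7.24 [-13.13, -5.31], 1 UMI in neonates), Lyz1 (-7.20), Zbtb7c (-6.20) and Slc7a2 (-6.09) were the lowest. Retnla and Lyz1 are also leading genes of cluster 25.4, left unnamed because its leading genes are dendritic. Markers of other cells differed with age in this class, neonates before adults. Dendritic ones were at 112 and 266 CPM, monocyte ones at 53.0 and 159, myofibre ones at 659 and 10.8 and erythroid ones at 186 and 28.0. Cluster 2 held 84.7% and 75.7% of macrophage-like cells in neonates and 97.0% and 34.9% in adults, control before injury. Cluster 10, led by Mmp12, Gpnmb and Hmox1, held 21.4% in the neonate injury library and 63.8% in the adult injury library. The median-of-ratios offset minus the CPM offset was -0.13, -0.11 and -0.22 in the age, neonatal and adult comparisons. Offsets are subtracted, so median-of-ratios scaling raised all log2 ratios of this class by the size of these values.

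Endothelial-like cells of the injured adult library stood above the control in basement membrane and cell cycle genes. Of 13 basement membrane genes, 11 were at least 2-fold higher and 0 lower with a median of 1.59 [1.02, 2.36], including Col18a1 (3.39), Nid2 (2.41) and Col4a1 (2.19). The 18 measured G2M genes were all at least 2-fold higher, with a median of 4.99 [4.21, 6.64]. The highest genes were Pclaf (7.55 [5.64, 13.45], 1 UMI in the control), the immune checkpoint gene Cd276 (7.32 [6.23, 9.09]), Top2a (6.79, 3 UMIs in the control), Ube2c (6.64, 2 UMIs in the control) and Mest (5.90). Cytl1 had 0 UMIs after injury and was at least 276-fold lower, and Gkn3 (-7.08 [-10.45, -5.54], 2 UMIs after injury), Penk (-5.68) and Mdga2 (-5.09) followed. Markers of other cells moved with injury in this class too, mural ones at 1039 against 363 CPM, dendritic ones at 514 against 85.8 and macrophage ones at 49.6 against 13.5. Angiogenesis genes divided, with Apln (5.19), Angptl4 (3.02), the tip cell gene Angpt2 (2.51) and Aplnr (2.48) higher and a list median of 0.26 [-0.86, 2.48]. Cluster 16 held 68.9% of endothelial-like cells in the adult control and 52.3% after adult injury, and cluster 12 held 29.7% after adult injury and 73.3% and 76.4% in the neonate control and injury libraries.

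After neonatal injury, endothelial-like cells stood below the control in stress and inflammatory genes. Hspa1a (-4.22 [-4.66, -3.83]) and its near-identical copy Hspa1b (-3.49), the growth factor gene Csf3 (-3.19), Cxcl1 (-2.73) and Gadd45b (-2.57) were the lowest, and H2ac24 (3.73), Nalf1 (3.71), Tll1 (3.10), Egfem1 (2.99) and Ptchd4 (2.68) the highest. Heat shock genes had a median of -1.17 [-1.59, -0.71] with 8 of 12 at least 2-fold lower, immediate early genes one of -1.10 [-1.46, -0.33] with 10 of 16, including Ier3 (-1.86), Junb (-1.66) and Btg2 (-1.56), and inflammatory cytokines and NF-kB targets one of -1.33 [-2.43, -0.42], with Il6 at -2.43 and Icam1 at -1.78. Markers of other cells in this class moved both ways, neutrophil ones at 1.33 CPM after injury and 81.5 in the control, erythroid ones at 627 and 3218, chondrocyte ones at 15.9 and 119 and tenocyte ones at 56.4 and 126, but B cell ones at 821 and 465, dendritic ones at 531 and 458, Schwann ones at 60.6 and 40.0 and macrophage ones at 25.1 and 17.4. Between the uninjured ages, H19 had 0 UMIs in adult endothelial-like cells and was at least 1056-fold higher in neonates, and the monooxygenase gene Fmo2 had 0 UMIs in neonates and was at least 738-fold lower. Fmo2 is a leading gene of cluster 30, which held 30.1% of endothelial-like cells in the adult control and 1.39% in the neonate control, so this value moves with that cluster. Mest (6.37), Prnd (6.07), Cdk1 (5.97) and H1f10 (5.41) followed at the neonatal end and Lnx1 (-6.54), Myrip (-6.26) and Xdh (-6.13) at the adult end; Prnd leads cluster 12, which held 73.3% in the neonate control. Neonates stood higher in basement membrane genes, with 10 of 12 at least 2-fold higher and a median of 1.36 [1.16, 2.15], and lower in MHC class I genes, with 9 of 10 at least 2-fold lower and a median of -1.38 [-2.158, -1.003], H2-Q7 (-4.00) and H2-K1 (-2.16) among them. Interferon response genes had a median of -1.10 [-2.30, -0.41], with Gbp2 at -2.58, Ifit3 at -2.57 and Rsad2 at -2.30. Markers of other cells differed with age in this class too. Erythroid ones were at 3218 CPM in neonates and 58.2 in adults, neutrophil ones at 81.5 and 0.624, chondrocyte ones at 119 and 6.65, dendritic ones at 458 and 85.8, myofibre ones at 103 and 12.5, B cell ones at 465 and 1678 and tenocyte ones at 126 and 396. Macrophage-like cells of the neonate control had lower sums, at 112 CPM for dendritic and 37.8 CPM for B cell markers. The dendritic and B cell sums thus need not come from dendritic or B cells.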

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

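The handling test across cell classes and the use of cells with Y-linked UMIs were chosen only after the results were seen. Thinning to 2000 UMIs was fixed before the data were examined, but the prediction of the depth test was written after. Results are listed here when the injury comparison pointed in opposite directions in neonates and adults with both intervals away from 0; in each case the difference was not tested, because each group held 1 library. In fibroblast-lineage cells the median log2 ratio was -1.26 in neonates and 1.80 in adults for S phase genes, -1.64 and 5.22 for G2M genes, -0.76 and 0.25 for ribosome biogenesis genes (the adult value turned to -0.047 without cycling cells), -1.51 and 0.80 for cholesterol synthesis genes and -1.68 and 0.36 for heat shock genes. In macrophage-like cells it was -1.43 and 0.85 for S phase genes and -1.78 and 3.52 for G2M genes. The adult cycling shares of that class had overlapping intervals. They were 0.602% [0.015, 3.31] in the control, from 1 of 166 cells, and 2.69% [1.82, 3.82] after injury. In endothelial-like cells it was -0.73 and 1.38 for matricellular genes and -0.63 and 0.31 for ribosome biogenesis genes. With doublets kept the matricellular medians were -0.48 and 0.62 and their difference -0.96 in place of -2.27. The cycling share of fibroblast-lineage cells was 2.72% in the injured neonate library, below its control at 7.57%, and 9.24% in the injured adult library, above its control at 0.240%.

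The opposite direction of the G2M genes was weighed against 3 technical explanations. If depth per cell were the cause, the order of libraries should be lost at 2000 UMIs per cell; the injured neonate share was then 3.87% [3.45, 4.33] against 10.2% in its control, and the adult shares were 14.0% and 0.166%, so the order was kept. If the different sex of the neonatal libraries were the cause, injured cells with Y-linked UMIs and no Xist should have a G2M median near 0; it was -1.68 [-1.88, -1.39]. If the mix of tenocyte-like and fibroblast-like cells were the cause, the direction should be lost within fibroblast-like cells; the median was -1.55 in neonates and 5.92 in adults. None of the 3 accounts for the direction in fibroblast-lineage cells. Age at injury, age at harvest and time from injury to harvest remain open, and none of these could be tested with these libraries.

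The lower tendon marker median of the injured adult library was weighed against a smaller part of tenocyte-like cells in the lineage. In tenocyte-like cells alone the median was 0.086 [-1.24, 0.73], which is consistent with that explanation. The class is named from markers of the same kind, so this test cannot tell a loss of tenocyte-like cells from a loss of marker RNA within cells.

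The lower heat shock median of the injured neonate library was weighed against tissue handling and sex. Handling should act on all classes, and the median was -1.68 in fibroblast-lineage, -1.17 in endothelial-like and -1.16 [-1.52, -0.58] in macrophage-like cells, which is consistent with a difference in handling. Injured fibroblast-lineage cells with Y-linked UMIs and no Xist had a median of -1.60 [-2.17, -0.87], so sex does not account for it in that lineage. In macrophage-like cells the median of such cells was -0.65 against -1.16 for all, and a part for sex there stays open. A response of all cell types to injury would give the same values and stays open. The same neonate control stood above the adult control in heat shock genes of the fibroblast lineage. With 1 library per group, a low injured library cannot be told from a high neonate control.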

How the results depend on the processing

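Alternatives with Y-linked cells, unnamed clusters and free-RNA members were chosen only after the results were seen. Of 2466 list medians under alternatives in the fibroblast lineage, 2412 stayed within the interval, 46 left it and 8 reversed, that is, changed sign where the interval lay away from 0. No median reversed in this sense in macrophage-like or endothelial-like cells. Counting medians with intervals that span 0, 127 of 2466 changed sign, as did 54 of 1072 in macrophage-like and 82 of 1103 in endothelial-like cells. Intervals of list medians are the spread among member genes, so a median can move far and stay within them. The adult injury median of small leucine-rich proteoglycans counted as within its interval, though it went from -1.95 to 0.19 in tenocyte-like cells alone. For genes of the lineage named in the text, 704 of 2202 values left the interval and 6 reversed; in endothelial-like cells 78 of 336 left it and in macrophage-like cells 30 of 339. Of 581 class share values 452 stayed within the interval, and 27 passed between 0 and a higher share. The causes below were not tested unless stated.

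Reversals came mostly with 1 class alone. The adult tendon marker median of -2.53 turned to 0.086 in tenocyte-like and 1.09 in fibroblast-like cells, and the neonate minus adult difference of 2.94 to -0.68 and -1.03. In tenocyte-like cells alone, the adult inflammatory cytokine median turned to -0.33, and the differences for BMP and GDF genes to -0.58 and for glycolysis genes to 0.067. Adult ribosome biogenesis turned to -0.047 without cycling cells. C7 turned to 0.36 in tenocyte-like and Col22a1 to 0.94 in fibroblast-like cells in the age comparison. In adult injury Fmod turned to 0.10 in tenocyte-like and 0.87 in fibroblast-like cells, Grem1 to -0.62 in tenocyte-like and Gdf5 to 3.95 in fibroblast-like cells.

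The cycling cells removed here held at least 2 G2M UMIs without thinning, so the removal depends on depth per cell. They made up 33.0%, 8.36%, 2.78% and 43.9% of the lineage in the order neonate control, neonate injury, adult control and adult injury. Without cycling cells the G2M median was 2.06 for age, -0.39 and 1.42 for neonatal and adult injury and -0.65 for the difference. The G2M shift is by construction, since these cells are chosen by G2M UMIs. The S phase median was then -1.01 and 0.59 for neonatal and adult injury and -1.49 for the difference. Neonatal G2M was -1.73 with the looser and -1.78 with the stricter filter, -1.79 with doublets kept and -2.05 in tenocyte-like cells; adult G2M was 5.92 in fibroblast-like cells, and the difference -7.42 in each class. Thinned to 1000 UMIs, adult S phase was 0.73 and its difference -2.28. Myofibroblast genes were at -0.31 in Y-linked cells and -0.36 in fibroblast-like cells after neonatal injury, and at 1.76 in tenocyte-like cells and 1.86 without cycling cells after adult injury. The age median of tendon markers was 0.96 in fibroblast-like cells.

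The fibroblast-lineage share of the neonate control was 53.8% (looser), 52.3% (stricter) and 51.3% (doublets kept). After neonatal injury it was 61.6% (looser), 64.3% (stricter), 60.3% (resolution 0.5) and 60.1% (resolution 2). In the adult control it was 63.2% (looser) and 65.9% (stricter), and after adult injury 39.4% (looser), 44.2% (stricter), 39.7% (doublets kept), 44.9% (resolution 0.5), 45.2% (resolution 2) and 45.6% (unnamed included). The macrophage-like share was 8.86% (doublets kept) and 10.6% (unnamed included) after neonatal injury, 3.47% (unnamed included) in the adult control, and 20.5% (each library clustered alone) and 28.0% (unnamed included) after adult injury. The endothelial-like share of the neonate control was 3.49% (looser), 4.34% (resolution 0.5), 3.72% (resolution 2), 4.60% (each library clustered alone) and 4.59% (unnamed included). After neonatal injury it was 6.10% (stricter), 2.54% (each alone) and 7.84% (unnamed included), in the adult control 12.2%, 10.96% and 14.2% in the same order, and after adult injury 10.9% (unnamed included). The neutrophil-like share after adult injury was 1.77% (stricter), and the chondrocyte-like share after neonatal injury 0.103% (looser) and 0.059% (stricter). Cycling shares at 500 UMIs were 5.25%, 2.03%, 0.080% and 5.51%, and at 2000 UMIs 10.2%, 3.87%, 0.166% and 14.0%. No paired analysis was possible because the groups share no animal or batch in the labels.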

Other observations

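Other gene groups of the adult injury comparison, chosen for description after the results were seen, add to the picture of fibroblast-lineage cells. Imprinted growth genes, which were higher in the neonate control than in the adult control, were also higher in the injured adult library than in the adult control. Of 14 genes, 10 were at least 2-fold higher, with a median of 1.52 [-0.01, 5.08], or 0.87 in tenocyte-like and 0.84 in fibroblast-like cells alone. H19 had a log2 ratio of 7.45, Slc38a4 of 5.09, Dlk1 of 5.08 and Mest of 4.27. Both comparisons divide by the same adult control library, so low values there raise both sets of ratios. The Wnt antagonist genes divided, with Sfrp1 (4.31) and Sfrp2 (4.27) higher and Wif1 (-4.76) lower after injury, and the list median was 0.37 [-1.05, 1.34]. Nerve growth and axon guidance genes did likewise, with Slit2 (3.37) and Gdnf (2.31) higher and Ntf3 (-2.70) lower, and a median of -0.24 [-1.40, 0.44]. The cell cycle inhibitor genes Cdkn2a (4.21) and Cdkn2b (2.38) were higher within a list whose median was 0.60, or 0.26 with each cell thinned to 1000 UMIs. Among elastic fibre genes Fbn2 (2.80), Emilin1 (2.61) and Eln (2.42) were higher and Fbln1 (-2.52) lower, with a median of 0.81 [-0.36, 2.42], or 0.31 in fibroblast-like cells alone. Hedgehog signalling genes had a median of -0.96 [-2.11, 0.20], with Gli2 at -2.11 and Boc at -1.59, and -0.48 in tenocyte-like cells alone.

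Other gene groups of the neonatal control, set against the adult control, included insulin-like growth factor genes, with 9 of 13 at least 2-fold higher and a median of 1.91 [-0.60, 5.38]. Igfbp2 (5.38) and the RNA-binding protein gene Igf2bp3 (3.32) were examples. Myofibroblast genes had a median of 1.00 [-0.07, 3.07], with Cthrc1 (4.97), Lrrc15 (4.10) and Postn (3.07) higher in neonates; the median was 1.84 in fibroblast-like cells alone and 3.07 without free-RNA members. The elastic fibre genes Fbn2 (3.92), Eln (2.90) and Mfap2 (2.69) stood higher within a list whose median was 0.73 [-0.91, 2.69], or 0.18 in tenocyte-like and 0.043 in fibroblast-like cells alone. The hedgehog target Gli1 (2.45) stood higher within a list whose median was 0.64 [-0.56, 2.90]. The neurotrophin receptor gene Ngfr had a log2 ratio of 3.77. After neonatal injury the imprinted genes Nnat (-2.54), Dlk1 (-2.03) and Cdkn1c (-1.72) were lower. They were picked for large absolute ratios and do not describe the list. Other members, Plagl1, H19 and Mest, are leading genes of cluster 18, which took 97.0% of its cells from the injured neonate library.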
